A study of Mus musculus with 16 samples.

How the data were processed

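Poly(A) RNA from CD45+ cells of bone marrow and spleen of C57BL/6J mice was sequenced in 16 libraries, 4 in each of 4 groups. Each deposited file holds 1 library as FPKM (fragments scaled by exon length and by the assigned fragments of the library) for 49585 Ensembl genes, a unit named in the file headers. The submitters name CASAVA 1.9, STAR 2.6.1a, featureCounts and edgeR 3.28.1 with the mouse build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited FPKM values carry no visible filter and no scaling for composition between libraries.

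Genes were matched by Ensembl identifier to GENCODE M21 (GRCm38), which gave 49326 of them (99.5%) a symbol. A gene's value is a sum over its exons. FPKM multiplied by the M21 exon length fell on whole multiples of 1 step per library, within 0.01 of a whole number, for 27922 of the 31954 genes above 0 (87.4%). For the remaining 4032 the smallest other length that gave whole numbers in all libraries was used, which need not be the only one. The step gives the assigned fragments of each library, 11.34 to 16.96 megafragments (M), and the reads behind each value, which served the filter, the scaling and the shares of reads. At these depths 1 fragment in a gene of 2 kilobases gives an FPKM of 0.0295 to 0.0441. Replicate libraries of a group had correlations of log2 FPKM of 0.971 to 0.9795 and differed beyond sampling noise, with a chi-square per degree of freedom of 6.61 to 41.48, so no library was a copy of another.

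The comparisons were planned, before the data were examined, for counts with the quasi-likelihood test. The deposited unit is FPKM. On the recovered reads edgeR and DESeq2 were not run, and limma 3.58.1 (R 4.3.3) was fitted to the FPKM values in their place. FPKM values were divided by TMM factors (trims of 30% and 5%) computed from the recovered reads by a reimplementation, and 0.1 was added before the log2. Fold changes on this scale are understated for genes with low FPKM. Genes needed 10 recovered reads or more in at least 4 libraries of a comparison. The fit used moderated statistics with a trend of the spread against the mean, two-sided tests and the Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p below 0.05. Where a value is given as a log2 change ± a number, the number is the standard error from limma with 4 libraries per group. FPKM values are given as mean ± SD of 4 libraries. Other values were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

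The comparisons were hM3Dq against mCherry within bone marrow and within spleen, the difference between these effects (an interaction over all 16 libraries), and bone marrow against spleen in the mCherry libraries. The overlap of the within-tissue calls was tested with Fisher's exact test, and 16 measures of the libraries with exact two-sided permutation tests. A total of 37 gene lists of responses, RNA quality and cell types, written before the data were examined, were tested with camera (limma) at a preset correlation of 0.01, on lists with at least 5 measured genes. The same lists were tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance.

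Genes were named by a rule written before the data were examined. For each tissue it took the 7 higher and 7 lower called genes with the smallest p whose hM3Dq and mCherry libraries did not overlap in FPKM, leaving out predicted models and antigen receptor segments. It added a panel of 10 genes and up to 4 members, smallest p first, of each list called by camera. For the interaction and the tissue comparison it took 4 genes in each direction, and the condition on overlap was not applied to the interaction. Called members of lists could also be named as examples. Results of some genes that the rule took are not reported here.

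The replicate numbers are 5 to 8 in the hM3Dq groups and 1 to 4 in the mCherry groups, in both tissues. The labels do not say whether a number stands for a mouse, so the main fits use no pairing and a replicate block is an alternative. No number occurs in both virus groups, so a batch that follows the numbers cannot be separated from the virus.

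The procedure was tested on simulated data with the same depths. All genes were given 1 dispersion, 0.00771, a median estimate from the data, and were drawn independently of each other. Genes in the data vary together and need not share 1 spread, so the shares and counts below may not hold for the data. In bone marrow 47.8% of genes changed 1.5-fold and 87.3% of genes changed 2-fold were called, in spleen 62.7% and 87.7%, for the interaction 18.2% and 65.2%, and between tissues 67.2% and 91.8%. Of the genes simulated without a change, 6 were called in bone marrow (16001 genes tested in all), 13 in spleen (17058), 4 for the interaction (17926) and 15 between tissues (16112).

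Alternatives planned before the data were examined were other scalings, other filters on low values, a minimum fold change, an adjusted p below 0.10, quality weights, a robust spread, a single fit of all 16 libraries, leaving out antigen receptor and haemoglobin genes, the replicate block, other list tests and each library left out in turn. Chosen after seeing the data were pseudocounts of 0.5 and 1, an FPKM filter of 0.5, voom on the recovered reads, the haemoglobin share as a covariate, list tests without composition scaling, list tests of the interaction and the share of rRNA-like genes as a library measure. Sequence-level data, splicing and antigen receptor repertoires were not analysed here.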

Results

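RNA was measured in CD45+ cells, the blood-lineage cells, of bone marrow and spleen of 12-week-old mice. A viral vector in the brainstem (VLM) of Dbh-Cre mice gave catecholaminergic neurons either hM3Dq, a designer receptor that clozapine N-oxide (CNO) activates, with mCherry, or mCherry alone as the control. Cells were collected 4 h after CNO, in 4 libraries for each virus and tissue. Assigned fragments per library, in megafragments (M), were 13.02 to 14.44 M in bone marrow hM3Dq, 12.55 to 15.9 M in bone marrow mCherry, 11.34 to 16.36 M in spleen hM3Dq and 13.15 to 16.96 M in spleen mCherry. The receptor is expressed in neurons of the brain, so its transcript is not a check on these cells. The question behind the comparisons was what activating these neurons does to immune cells of the marrow and the spleen, including the genes by which such cells home to a tissue.

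In bone marrow, the hM3Dq libraries had higher transcripts of genes that glucocorticoid hormones induce. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527 in GRCm38), a co-chaperone of the glucocorticoid receptor, stood at 54.6 ± 4.38 FPKM against 10.3 ± 0.237 in mCherry libraries (SD, n = 4 each). It was 4.99-fold higher. Ddit4, an inhibitor of mTORC1 signalling, rose from 5.30 ± 1.01 to 46.9 ± 6.88 FPKM, Per1, a core clock gene with glucocorticoid response elements, from 3.27 ± 0.327 to 27.4 ± 9.52, and Il1r2, a decoy receptor for interleukin-1, from 18.4 ± 3.45 to 119 ± 34.1. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 14.5 ± 3.30 to 49.0 ± 2.99 FPKM and Il7r, the interleukin-7 receptor, from 9.15 ± 0.783 to 17.6 ± 2.70.

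The log2 changes in bone marrow were 2.32 ± 0.08 for Fkbp5 (adjusted p = 1.92e-06), 3.06 ± 0.14 for Ddit4 (1.55e-05) and 2.89 ± 0.23 for Per1 and 2.58 ± 0.21 for Il1r2 (both 7.54e-04). They were 1.71 ± 0.15 for Tsc22d3 (adjusted p = 8.60e-04) and 0.86 ± 0.11 for Il7r (0.00632). Crispld2 (adjusted p = 3.54e-04), Foxred2 (1.37 ± 0.10) and Map3k6, a stress-activated kinase (1.68 ± 0.13), completed the 7 higher genes taken by smallest p among genes whose groups did not overlap. The 7 lower genes in bone marrow included Elovl7, a fatty acid elongase (-1.34 ± 0.16, adjusted p = 0.00377), and Rbm14 (-0.81). The others were Il1a, which encodes interleukin-1 alpha (-1.34 ± 0.17), Chtf8 (-0.63), n-R5s183 (-1.35), Dynll1, a dynein light chain (-0.92), and the chaperone gene Hsph1 (-0.91 ± 0.12, adjusted p = 0.00698). The same rule gave the lower genes. Of the panel, Cxcr4, the receptor that holds cells in the marrow, was not called in bone marrow (246 ± 11.4 against 184 ± 22.0 FPKM, log2 change 0.35 ± 0.09, adjusted p = 0.066), though it was called higher in 5 of 21 other fits (lowest adjusted p = 0.0295). S1pr1 (-0.14), Ccr7 (0.03) and the glucocorticoid receptor gene Nr3c1 (0.07) were not called either, with adjusted p from 0.572 to 0.931. The sign of the Ccr7 and Nr3c1 values turned under other settings.

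Across the transcriptome of bone marrow, limma called 781 of 16095 genes, 505 higher and 276 lower (64.7% higher), and 192 of them changed at least 2-fold. Without scaling for composition the split was 640 higher and 158 lower, so the balance of directions depends on that step. The count was 345 without hM3Dq replicate 6, 449 without hM3Dq replicate 8, and 478, 271 and 274 without mCherry replicates 1, 2 and 4.

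**Figure D1:**
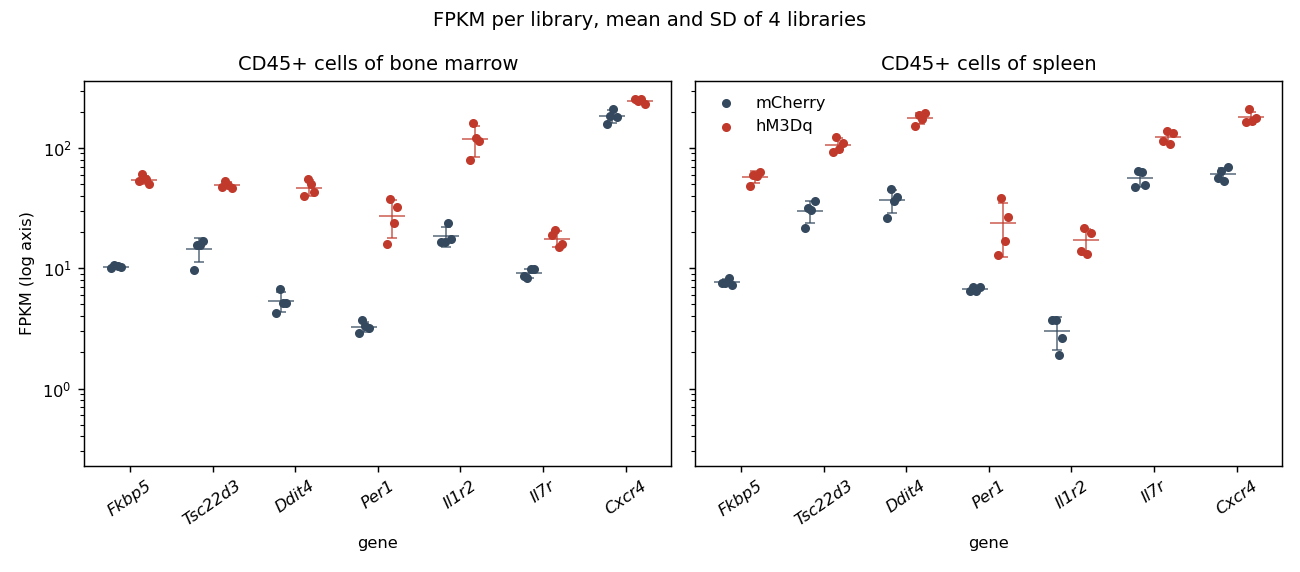
FPKM (log axis) of named genes in bone marrow and spleen, with 1 point per library and the mean and SD of the 4 hM3Dq and 4 mCherry libraries. Fkbp5 had a mean of 54.6 FPKM in bone marrow hM3Dq libraries and 57.6 in spleen hM3Dq libraries, against 10.3 and 7.66 in the mCherry libraries.

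Of the 27 measured genes of the glucocorticoid-induced list, 16 rose in bone marrow and none fell (20 adjusted over the list alone), with a list median of 0.82 (camera adjusted p = 1.80e-16; adjusted p = 0.363 with an estimated correlation). Besides the genes above they included Klf9 (2.17), a transcription factor that responds to glucocorticoids, Dusp1 (2.59), a phosphatase that turns off MAP kinases, Zbtb16 (2.05) and Nfkbia (1.12), the inhibitor of NF-kB. The type I interferon list moved down, with 5 of 30 genes lower (21 adjusted over the list alone) and a median of -0.63 (adjusted p = 2.85e-11; adjusted p = 0.768 with an estimated correlation). Its lower genes included the antiviral sensor gene Oas3 (-0.79 ± 0.13, adjusted p = 0.0149), Isg15 (-1.45), Usp18 (-1.29) and Cmpk2 (-0.67). The circadian clock list had a median of 0.28 (adjusted p = 0.0104; adjusted p = 0.768 with an estimated correlation) and 3 of 16 genes higher on either adjustment: Tef (0.76 ± 0.12), Nfil3 (0.78) and Cry2 (0.57). The mature neutrophil list had a median of 0.20 (adjusted p = 0.0104, and 0.898 with an estimated correlation) and 4 of 25 genes higher (6 adjusted over the list alone). Among them were Il1r2, also a member of the glucocorticoid-induced list, and Cxcl2, a neutrophil attractant (3.48 ± 0.76). The call of Cxcl2 ended in 7 fits that left out 1 library and in 6 other settings. Of the 4, only Il1r2 kept its call with each library left out. The clock median was 0.16 without hM3Dq replicate 6, 0.15 with a pseudocount of 1 and 0.12 with the haemoglobin covariate, and the mature neutrophil median 0.09 without mCherry replicate 1.

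Several lists moved down in bone marrow with few single genes called. The erythroid list had a median of -0.78 and the cell cycle list of -0.22, both with an adjusted p of 8.80e-06 (adjusted p = 0.898 with an estimated correlation for both). None of their 26 and 38 genes was called on either adjustment. Klf1, the erythroid master regulator, stood at -0.99 ± 0.36, Epb42 at -1.05, the mitotic kinase gene Plk1 at -0.43 and Top2a at -0.31. The haemoglobin share of reads, 1.40 ± 1.07% against 2.01 ± 0.655%, was lowest in hM3Dq replicates 5 (0.564%) and 6 (0.391%). Cholesterol synthesis had a median of -0.22 (adjusted p = 0.0036; adjusted p = 0.898 with an estimated correlation) and no gene of 21 called, though 4 were lower adjusted over the list alone. Cyp51 was at -0.56 and Mvk at -0.45. Heat shock and unfolded protein genes had a median of -0.20 (adjusted p = 0.00424; adjusted p = 0.768 with an estimated correlation), with Hsph1 lower and Herpud1 (0.78) higher among 23 genes (6 lower and 1 higher adjusted over the list alone). Oxidative phosphorylation had a median of -0.09 and none of 35 genes called on either adjustment (adjusted p = 0.0251; adjusted p = 0.960 with an estimated correlation), with Ndufb3 at -0.35. The plasmacytoid dendritic cell list (median -0.23, adjusted p = 0.0358; adjusted p = 0.768 with an estimated correlation) had Cox6a2 (-0.66) lower among 14 genes, and 4 adjusted over the list alone. The fatty acid oxidation list (median -0.14, adjusted p = 0.0497; adjusted p = 0.898 with an estimated correlation) had Cpt2 (-0.49), an enzyme of mitochondrial fatty acid import, lower among 20 genes, and 2 adjusted over the list alone. Without hM3Dq replicate 6 the erythroid median was -0.43 and the cell cycle median -0.14, and with the haemoglobin covariate they were -0.16 and -0.08. The oxidative phosphorylation median was -0.05 without hM3Dq replicate 5 and -0.15 without mCherry replicate 1. The fatty acid oxidation median was -0.09 and -0.08 without hM3Dq replicates 5 and 8, and the plasmacytoid dendritic cell median -0.35 without mCherry replicate 3. Without composition scaling the heat shock median was -0.13.

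The other lists were not called in bone marrow by camera. Homing and adhesion receptors had a median of -0.03 with none of 28 genes called, and the pan T cell list a median of -0.05 with none of 24 called, and both signs turned under other settings. With the haemoglobin share as a covariate the homing list was called lower (median -0.13, adjusted p = 0.0353). The mature B cell list had a median of 0.06, a mean of -0.08 and a test in the lower direction, with 1 of 20 genes called, Fcer2a (-0.94), the low-affinity IgE receptor. The list of death genes that glucocorticoids induce in lymphocytes had a median of -0.01 and a mean of 0.12, with Bmf (1.16) and Trp53inp1 (0.92) higher among 13 genes. The plasma cell list had a median of 0.13 (adjusted p = 0.201), with 4 of 19 genes called, all higher. The immature neutrophil list had a median of -0.06 and 16 of 22 genes below 0, but 3 called, all higher. Adjusted over the list alone, 3 of its genes were higher and 2 lower, and in the plasma cell list 4 and 1. Among the cAMP and immediate early genes, with a median of 0.07, the transcription factor gene Cebpb was higher (1.26). Median, mean and test also differed in sign for the chemokine, T helper, glycolysis, mitochondrially encoded, pan T cell, CD4 T cell and monocyte lists, none of them called.

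Camera called 11 of 37 lists in bone marrow, 3 higher and 8 lower. None was called with an estimated correlation, and fry called 1, the glucocorticoid-induced list (adjusted p = 7.23e-04). Of the 35 ways to split the 8 libraries into equal groups, 14 called 11 lists or more, so the number of lists is within what other splits gave. As large a list median came from 1 split, the real one, for 4 of the 11 lists. That is the smallest share 35 splits allow and was not adjusted over the 37 lists, so it does not by itself exclude chance. For the rest as large a median came from 2 to 10 of 35 (10 for oxidative phosphorylation, 9 for erythroid), so chance is not excluded there either. With the haemoglobin covariate camera called 13 lists, of which 9 were among the 11. With 1 library left out, the calls of Isg15, Cmpk2, Usp18, Nfil3, Cry2, Cxcl2, Cpt2, Cox6a2, Herpud1 and Fcer2a ended in 3 to 7 of the 8 fits, and leaving out mCherry replicate 4 ended all 10. Having no filter ended the same 10 (adjusted p from 0.0545 to 0.114), and the haemoglobin covariate those of Usp18, Nfil3, Cry2, Cpt2, Cxcl2, Cox6a2 and Herpud1. Among all genes followed through the settings, some not named here, the FPKM filters of 1 and 0.5 ended 4 calls each. A single fit of all 16 libraries, no composition scaling, a robust spread and voom ended 2 each. With a pseudocount of 1 the changes were -0.87 for Elovl7, -0.59 for Il1a, 0.38 for Cry2, 1.72 for Cxcl2 and 1.32 for Zbtb16. The fatty acid oxidation, oxidative phosphorylation and plasmacytoid dendritic cell lists each lost their call in 3 or 4 of these fits, and the mature neutrophil list without mCherry replicate 1 (adjusted p = 0.103).

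In spleen, the hM3Dq libraries also had higher transcripts of glucocorticoid-induced genes, and lower transcripts of interferon-response and mature B cell genes. Fkbp5 stood at 57.6 ± 6.39 FPKM against 7.66 ± 0.459 in mCherry libraries (SD, n = 4 each). It was 7.28-fold higher. Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293), the receptor for the chemokine CXCL12, rose from 60.7 ± 7.56 to 179 ± 20.3 FPKM, 2.90-fold. Ddit4 rose from 36.6 ± 8.02 to 177 ± 19.1 FPKM, Tsc22d3 from 30.1 ± 6.28 to 106 ± 14.1, Per1 from 6.72 ± 0.288 to 23.7 ± 11.4, Il1r2 from 3.00 ± 0.906 to 17.1 ± 4.19 and Il7r from 56.3 ± 9.09 to 124 ± 15.1.

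The log2 changes in spleen were 2.86 ± 0.10 for Fkbp5 (adjusted p = 7.84e-06), 3.46 ± 0.16 for Trnp1 (4.23e-05) and 1.85 ± 0.11 for Pik3ip1, an inhibitor of PI3-kinase (3.37e-04). They were 1.54 ± 0.10 for Cxcr4 (adjusted p = 3.37e-04), 3.88 ± 0.25 for Ston1, 1.45 ± 0.10 for Ppp1r21 and 2.26 ± 0.17 for Ddit4 (8.40e-04). The 7 lower genes in spleen included Nfkbie, an inhibitor of NF-kB that NF-kB itself induces (-0.68 ± 0.05, adjusted p = 8.40e-04), Kynu, an enzyme of tryptophan breakdown (-1.15 ± 0.10, adjusted p = 0.00171), and Slc9a7 (-0.82). The others were the heparanase gene Hpse (-0.85), Egr3, an early-response transcription factor (-1.35 ± 0.14), L3mbtl3 (-0.58) and Snord35b (-0.85). These 14 genes were taken by the same rule. Of the panel, Tsc22d3 (1.81 ± 0.16), Per1 (1.66 ± 0.28) and Il7r (1.11 ± 0.14) were higher and S1pr1, the receptor by which lymphocytes leave lymphoid organs, was lower (-0.50 ± 0.08, adjusted p = 0.0112). Ccr7 (0.06) and Nr3c1 (-0.07) were not called, with adjusted p of 0.762 and 0.645, and the sign of the Ccr7 value turned under other settings.

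Across the transcriptome of spleen, limma called 1368 of 17076 genes, 581 higher and 787 lower (42.5% higher), and 223 of them changed at least 2-fold. The count was 859, 713 and 404 without hM3Dq replicates 6, 7 and 8, and 478, 742, 616 and 556 without mCherry replicates 1, 2, 3 and 4.

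Of the 27 measured genes of the glucocorticoid-induced list, 16 rose in spleen and none fell (19 higher and 1 lower adjusted over the list alone), with a median of 1.11 (adjusted p = 3.27e-17; adjusted p = 0.211 with an estimated correlation). They included Klf9 (1.75), Dusp1 (1.87), Txnip (1.32), which limits glucose uptake, and Sesn1 (1.39). In the type I interferon list 20 of 30 genes fell (28 adjusted over the list alone) and the median was -0.71 (adjusted p = 7.70e-16; adjusted p = 0.399 with an estimated correlation), with Usp18 at -0.94 (adjusted p = 0.00997) and Ifi27l2a at -0.89. The mature B cell list had 11 of 20 genes lower (14 adjusted over the list alone) and a median of -0.44 (adjusted p = 5.18e-10; adjusted p = 0.399 with an estimated correlation). Cr2, the complement receptor of follicular and marginal zone B cells (-1.18 ± 0.14, adjusted p = 0.00495), the signalling adaptor Bank1 (-0.92 ± 0.11), Fcer2a (-0.92), Ms4a1, which encodes CD20 (-0.77 ± 0.10), and Cd83 (-0.68) fell. In the same list Cd79a (-0.22), Cd79b (-0.09) and Ighd (-0.07) were not called, and the Ighd value turned sign without mCherry replicate 4 (0.0149).

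Genes of cell traffic and activation changed in spleen as well. Of 30 homing and adhesion receptors 6 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00504; adjusted p = 0.550 with an estimated correlation). They were Ccr2, the monocyte receptor for CCL2 (-0.98 ± 0.16, adjusted p = 0.0131), S1pr1, Itgal, a subunit of the integrin LFA-1 (-0.45), and Gpr183 (-0.44) among the lower genes, and Cxcr4 as the higher one. Of 23 cAMP and immediate early genes 6 fell, among them Egr3 and Egr1 (-0.77), and Dusp2 (0.71) rose (9 and 2 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.0201; adjusted p = 0.491 with an estimated correlation). Of 15 chemokines and niche ligands Cxcl10 (-2.08 ± 0.39), Ccl4 (-0.94), Cxcl9 (-0.78) and Icam1 (-0.54) fell and Vcam1 (0.90) rose (8 and 1 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.0201; adjusted p = 0.491 with an estimated correlation). Of 15 T helper effector genes Ifng, the interferon gamma gene (-0.98), its activator Tbx21 (-0.84) and Bcl6, the regulator of follicular helper T cells (-0.73), fell, and Ctla4 (1.28), an inhibitory receptor, rose (6 and 1 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0109; adjusted p = 0.511 with an estimated correlation).

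Lists of cholesterol synthesis, the clock, stress proteins and the cell cycle were called in spleen too. Cholesterol synthesis had 6 of 21 genes lower (10 adjusted over the list alone), among them Idi1 (-0.95 ± 0.13, adjusted p = 0.00779), Hmgcs1 (-0.73) and Cyp51 (-0.70), and a median of -0.26 (adjusted p = 3.72e-04; adjusted p = 0.491 with an estimated correlation). The circadian clock list had 3 of 17 genes higher, Nr1d2, Tef and Cry2, each with a change of 0.56 (5 adjusted over the list alone), and a median of 0.26 (adjusted p = 0.00575; adjusted p = 0.399 with an estimated correlation). Among 22 heat shock and unfolded protein genes 3 fell, among them Hsph1 (-0.85) and Calr (-0.45), a chaperone gene of the endoplasmic reticulum, and Herpud1 (0.47) rose (8 and 2 adjusted over the list alone; list median -0.19, adjusted p = 0.0226; adjusted p = 0.706 with an estimated correlation). The cell cycle list had a median of -0.28 and none of 38 genes called on either adjustment (adjusted p = 0.00804; adjusted p = 0.812 with an estimated correlation), with Mcm6 at -0.24 and Pcna at -0.26, beside an erythroid list that was not called at a median of -0.52 (0.23 with the haemoglobin covariate). The cell cycle median was -0.45 without hM3Dq replicate 5, -0.06 without hM3Dq replicate 6 and -0.16 without mCherry replicate 1, and the heat shock median -0.12 without hM3Dq replicate 6. The mitochondrially encoded list (median 0.23, adjusted p = 0.00138; adjusted p = 0.550 with an estimated correlation) and the cytosolic ribosomal proteins (0.10, adjusted p = 0.00472; adjusted p = 0.812 with an estimated correlation) had none of 13 and 44 genes called on either adjustment. The gene mt-Nd1 stood at 0.39 and Rps27 at 0.22. The ribosomal protein median was 0.06 without hM3Dq replicate 8, 0.17 without mCherry replicate 2 and 0.07 without mCherry replicate 4.

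Further cell type lists were called in spleen with smaller shifts. Dendritic cell genes had a median of -0.23 (adjusted p = 0.00504; adjusted p = 0.511 with an estimated correlation), with 3 genes lower, among them Cd209a (-0.70), and Flt3 (1.00), a growth factor receptor of progenitors and dendritic cells, higher among 17 (9 and 1 adjusted over the list alone). Monocyte genes had a median of -0.19 (adjusted p = 0.0201; adjusted p = 0.760 with an estimated correlation), with 3 genes lower among 23, Ccr2 and Ms4a4c (-0.91) among them (6 adjusted over the list alone). MHC class II presentation had a median of -0.16 (adjusted p = 0.0220; adjusted p = 0.550 with an estimated correlation) and H2-DMb2 (-0.41) lower among 13 (2 adjusted over the list alone). The immature neutrophil list had a median of 0.45 (adjusted p = 0.00679; adjusted p = 0.760 with an estimated correlation) and none of 22 genes called on either adjustment, with Orm1 at 1.10 and Mmp8 at 0.95. The megakaryocyte list (median 0.16, adjusted p = 0.0385; adjusted p = 0.550 with an estimated correlation) had Gp1ba (0.77) higher among 18, and none adjusted over the list alone. The stromal and endothelial list (median 0.24, adjusted p = 0.0487; adjusted p = 0.550 with an estimated correlation) had Tagln (0.86) higher among 12, and 2 adjusted over the list alone. Without hM3Dq replicate 6 the median was -0.09 for monocyte, 0.72 for immature neutrophil, 0.34 for megakaryocyte and 0.40 for stromal genes. The megakaryocyte median was 0.06 and 0.26 without hM3Dq replicates 7 and 8. Without mCherry replicate 3 the immature neutrophil median was 0.24 and the stromal median 0.38.

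Among lists that camera did not call in spleen, the death list held 4 higher genes of 13, Bbc3 (1.56), Bmf (1.11), Bcl2l11 (1.06) and Trp53inp1 (0.80), which promote cell death, beside a median of -0.03 and a mean of 0.27 (adjusted p = 0.196; called higher by fry, adjusted p = 0.0444). The NF-kB list (median -0.12, adjusted p = 0.0837; called lower by fry, adjusted p = 0.0207) had 5 of 19 genes lower, among them Nfkbie and the costimulatory receptor gene Cd40 (-0.86), and 1 higher. Fry also called the plasmacytoid dendritic cell list lower (median -0.12, adjusted p = 0.0271, with camera 0.0824). The fatty acid oxidation list (median -0.02, adjusted p = 0.504) had 3 of 22 genes lower, among them Cpt1a (-0.90), which controls fatty acid entry into mitochondria, and 1 higher. The plasma cell list (median 0.08, adjusted p = 0.0982) had 3 of 19 genes higher, among them Igha (1.23), the IgA heavy chain gene. Adjusted over the list alone, 4 genes were higher and 2 lower in the death list. In the NF-kB list these were 3 and 5, and in the plasma cell list 5 and 1. Oxidative phosphorylation (median -0.08, adjusted p = 0.0663) and glycolysis (-0.02, adjusted p = 0.926) were not called. The pan T cell list had a median of -0.13 (adjusted p = 0.402) and the NK cell list of -0.02 (adjusted p = 0.555). Median, mean and test differed in sign for the death, glycolysis, NK cell, mature neutrophil and macrophage lists, none of them called.

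Camera called 19 of 37 lists in spleen, 7 higher and 12 lower. None was called with an estimated correlation, and fry called 13, of which 10 were among the 19. Of the 35 splits of the 8 libraries 3 called 19 lists or more. The real split alone gave as large a median for 8 of the 19 lists. That share, the smallest possible, was not adjusted over the 37 lists and does not by itself exclude chance. For the rest 2 to 16 of 35 did (16 for the cell cycle, 15 for megakaryocyte), so chance is not excluded there either. Of the genes named above, the calls of Cxcl9, Cd209a, Gp1ba, Cry2 and Vcam1 each ended in 7 of the 8 fits that left out 1 library, those of Tef, Ctla4, Bmf, Ccl4, Tagln, H2-DMb2 and Ifng in 3 to 6, and those of Egr1, Itgal, Cxcl10 and Nr1d2 without hM3Dq replicate 8 alone (adjusted p from 0.0507 to 0.0589). A single fit of all 16 libraries ended the calls of Tbx21 (adjusted p = 0.0623), Ifi27l2a (0.0503), Ifng, H2-DMb2, Cd209a, Gp1ba and Cxcl9. Having no filter ended those of Cxcl9, Cxcl10, Ccl4, Ifng, Tef, Cry2, Cd209a, Gp1ba, Tagln, Ctla4, Vcam1 and Bmf, and the haemoglobin covariate those of Cxcl9, Cry2, Cd209a, Gp1ba and Vcam1. With a pseudocount of 1 the changes were 2.01 for Trnp1, 2.41 for Ston1, -1.06 for Cxcl10, -0.50 for Ifng, -0.63 for Idi1 and 0.42 for Gp1ba, and the list medians 0.66 for glucocorticoid-induced and -0.17 for immediate early genes. The immediate early list lost its call without hM3Dq replicate 7 (adjusted p = 0.0816) and the cell cycle list without hM3Dq replicate 6 (0.412) or mCherry replicate 1 (0.204).

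**Figure D2:**
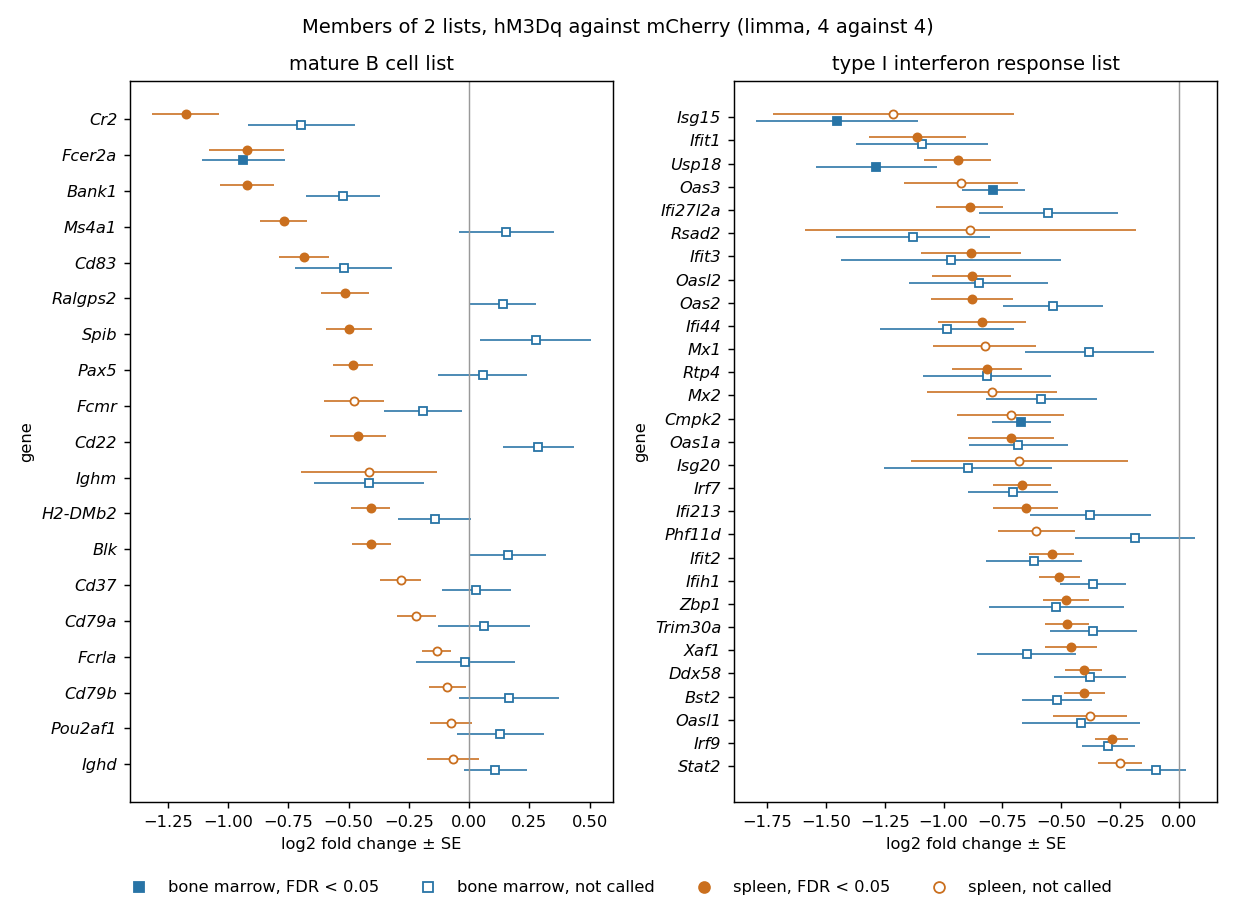
Log2 change ± SE (limma, 4 against 4) of members of the mature B cell and type I interferon lists in bone marrow (squares) and spleen (circles), filled where the gene was called. In spleen Cr2 stood at -1.18 and Usp18 at -0.94, and 1 member of each list is not shown.

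**Figure D3:**
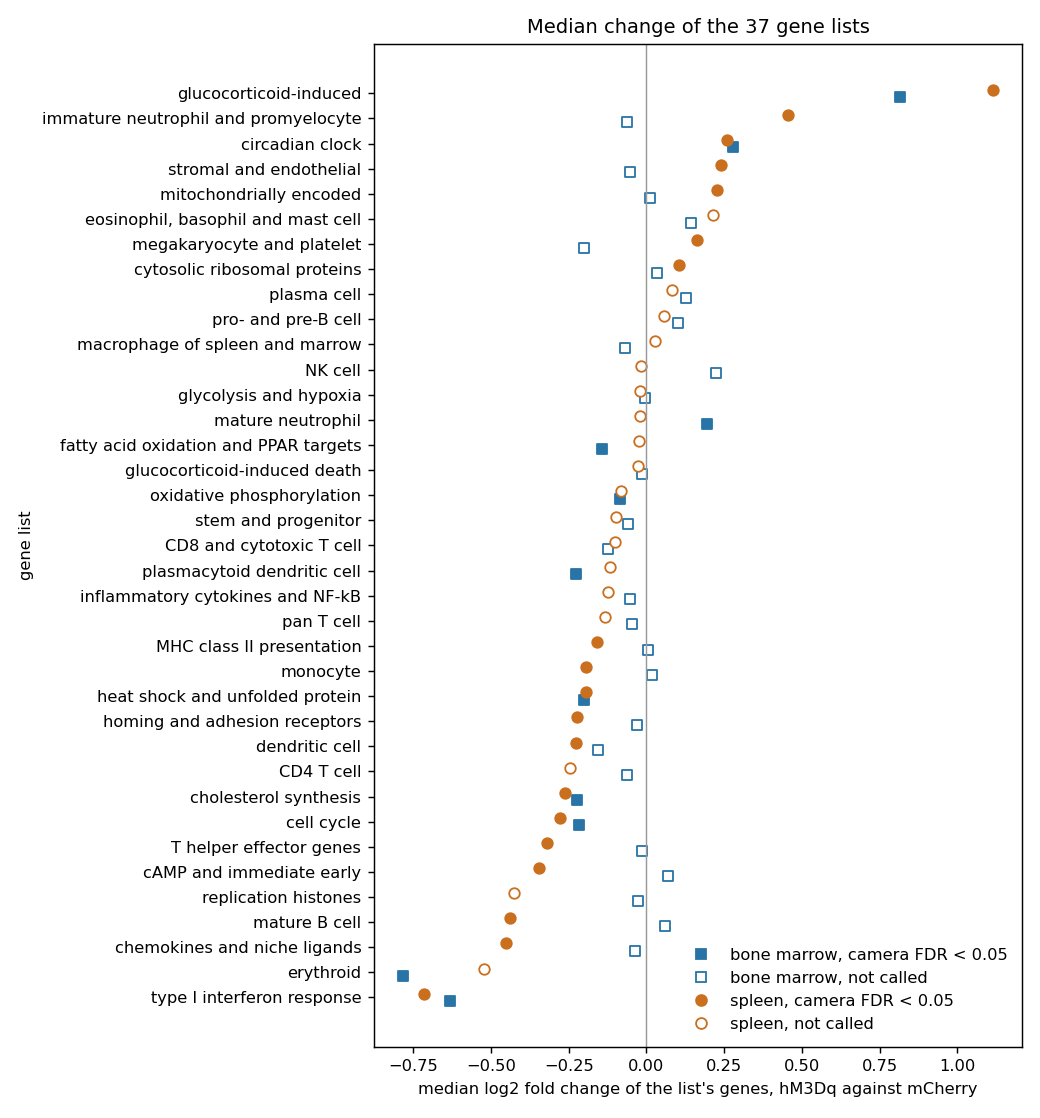
Median log2 change of the genes of each of the 37 lists in bone marrow (squares) and spleen (circles), filled where camera called the list at the preset correlation. The glucocorticoid-induced list had the highest medians, 0.82 and 1.11. No list was called with an estimated correlation, which called none between bone marrow and spleen either.

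The changes in the 2 tissues were set beside each other to see which genes moved in both. Among 15378 genes tested in both, 195 were higher in both and 93 lower in both, against 16.97 and 12.24 for independent lists (Fisher's exact test, p = 4.91e-164 and 2.11e-57), and no gene was called in opposite directions. Of 747 bone marrow calls tested in spleen 92.6% had the same sign there, and of 1258 spleen calls 89.7% had the same sign in bone marrow. Fisher's test takes the genes as independent, which they are not, so its p-values do not measure the chance of such an overlap. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.62. Each tissue has its own control libraries, which may come from the same mice, and the lists would then not be independent. The count of 288 shared genes changed with 1 replicate number left out of both tissues. It fell to 104, 100, 141 and 91 without mCherry replicates 1, 2, 3 and 4. Without hM3Dq replicates 6, 7 and 8 it fell to 117, 147 and 89, and without hM3Dq replicate 5 it rose to 327.

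**Figure D4:**
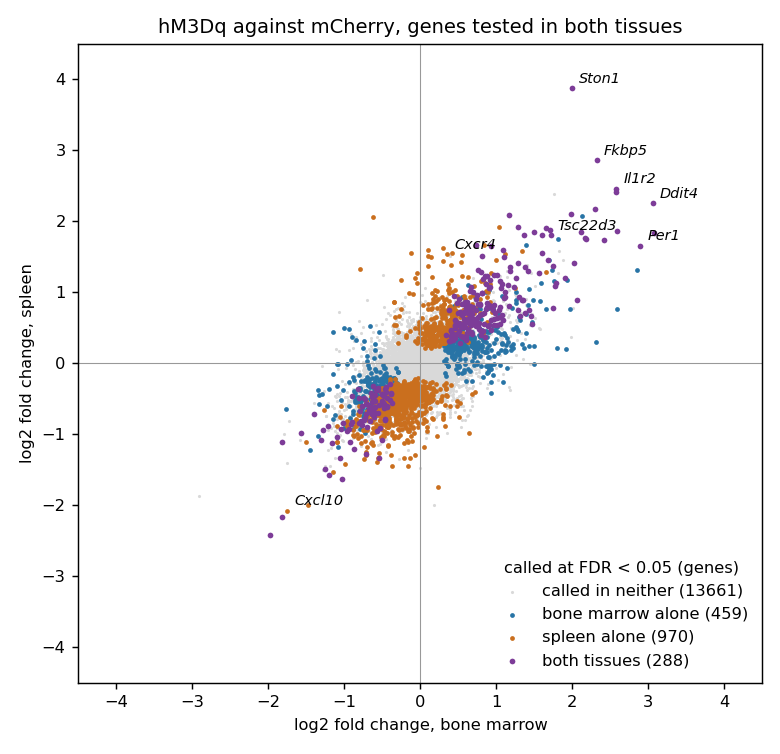
Log2 change of each gene in bone marrow (horizontal) and spleen (vertical), with 15378 genes coloured by where they were called. A total of 459 genes were called in bone marrow alone, 970 in spleen alone and 288 in both, and none of the 288 changed in opposite directions.

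The test of the difference between tissues asked for which genes the log2 change differed between marrow and spleen. The tissues hold different mixes of cells. Whether a difference lies in the response or in which cells carry the transcript was not tested. Cxcr4 was at 1.54 in spleen and 0.35 in bone marrow, a difference of -1.19 ± 0.13 (adjusted p = 0.00233). Bbc3, which encodes the pro-apoptotic protein PUMA, was at 1.56 in spleen and -0.12 in bone marrow, a difference of -1.69 ± 0.20 (adjusted p = 0.00281). Ppp1r21, an endosomal protein gene, differed by -1.15 (0.30 in bone marrow, 1.45 in spleen; adjusted p = 0.00233) and Ccnd3, the cyclin D3 gene, by -0.75 (-0.30 and 0.45; adjusted p = 0.0268). In the other direction Samsn1 (1.14 and -0.06), Ptp4a1 (1.34 and 0.27), Pla2g3 (1.09 and -0.27) and Tank (0.33 and -0.34) were higher in bone marrow relative to spleen, with adjusted p from 0.0364 to 0.0398.

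The interaction called 17 of 17987 genes, 7 with the higher change in bone marrow and 10 with the higher change in spleen, and 1554 had an unadjusted p under 0.05. Ppp1r21, Cxcr4 and Bbc3 stayed called with each single library left out, whereas Samsn1, Ptp4a1, Pla2g3, Tank and Ccnd3 lost the call in 7 to 13 of those 16 fits (adjusted p up to 0.110), and each fit but that without spleen hM3Dq replicate 5 ended at least 1 of them. The count was 37 without spleen hM3Dq replicate 5, 4 without spleen hM3Dq replicate 6 or 8 or mCherry replicate 3, 3 without spleen hM3Dq replicate 7 or mCherry replicate 1 or 4, and 7 without spleen mCherry replicate 2. It was 10, 8 and 6 without bone marrow hM3Dq replicates 5, 6 and 7, and 6, 5, 9 and 6 without bone marrow mCherry replicates 1, 2, 3 and 4. With a replicate block the count was 9, of which 5 were among the 17, and Samsn1, Ptp4a1, Pla2g3 and Tank were not called (adjusted p from 0.144 to 0.173). Pla2g3 and Tank were not called without a filter either, Pla2g3 not with voom and Tank not without composition scaling, and with a pseudocount of 1 the difference for Pla2g3 was 0.41.

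Bone marrow and spleen of mCherry mice were compared to describe the cells each tissue contributed. Genes of T cells, NK cells, mature B cells and antigen presentation were lower in bone marrow: 24 of 24 pan T cell genes (median -3.63), 15 of 15 NK cell genes (-2.86), 20 of 20 mature B cell genes (-2.64), and 12 of 13 MHC class II genes (-2.77). Genes of B cell precursors went the other way, with 16 of 20 pro- and pre-B cell genes higher in bone marrow and 3 lower (median 2.01). Genes of blood formation were higher in bone marrow: 22 of 22 immature neutrophil genes (median 4.69), 21 of 23 mature neutrophil genes (2.89), 17 of 18 stem and progenitor genes (1.84), 23 of 26 erythroid genes (1.69) and 38 of 38 cell cycle genes (1.96). By smallest p the higher genes were Ap3s1 (2.51), Clec12a (2.95), an inhibitory receptor of myeloid cells, Gapt (2.28) and Plau (3.52). The lower genes were Gimap8 (-4.10), Rasgrp3 (-3.81), Cd22 (-3.80), a B cell receptor inhibitor, and the cytokine receptor gene Il27ra (-3.68). Over the higher and lower genes together the adjusted p ran from 1.16e-08 to 5.84e-08.

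Between tissues limma called 11740 of 16943 genes, 5759 higher and 5981 lower in bone marrow, and 5089 differed at least 2-fold. Without scaling for composition the split was 4083 higher and 7977 lower, and the median of all genes moved by -0.24, so changes are relative to the scaling. Camera called 25 lists, none with an estimated correlation (lowest adjusted p = 0.210), and fry called 35. With an estimated correlation even the pan T cell list was not called, though 24 of its 24 genes were. A list that is not called with an estimated correlation, here or within a tissue, may therefore still have changed.

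Shares of reads describe the libraries themselves. In bone marrow the immunoglobulin share was 1.11 ± 0.176% in hM3Dq and 0.755 ± 0.0801% in mCherry libraries (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allows; adjusted p = 0.305), and all 4 hM3Dq values were above the mCherry values. The 100 highest genes took 32.3% and 36.2% of reads (exact permutation p = 0.0571). In spleen the mitochondrial share was 1.52 ± 0.179% and 1.27 ± 0.0772% (exact permutation p = 0.0857), and the haemoglobin share 0.960 ± 0.556% and 1.24 ± 0.475% (exact permutation p = 0.486). The share of rRNA-like genes, a measure chosen after seeing the data, was 15.3 ± 2.08% in hM3Dq and 19.1 ± 2.96% in mCherry libraries of bone marrow (exact permutation p = 0.0857) and 16.5 ± 2.20% and 18.6 ± 1.15% in spleen (exact permutation p = 0.114). None of the 16 measures was called after adjustment, and at an unadjusted p under 0.05 there was 1. With 4 against 4, most measures would have to reach the smallest p for any to be called.

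Some named genes share exons with another annotated gene, so their reads may belong in part to it. Chtf8 (91.8% of its exon bases) and Ptp4a1 (70.8%) overlap a second annotated gene of the same name, Snord35b lies wholly within another gene, Ifng shares 25.9% with Gm49751 and Rbm14 18.6% with Gm21992. Tagln (62.4%), Hmgcs1 (12.1%), Icam1 (11.7%), Il1a (11.2%) and Cox6a2 (10.3%) overlap genes on the opposite strand, and n-R5s183 is 1 of many 5S ribosomal RNA copies. These values are uncertain for the named gene.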

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

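The tests of a changed cell mix, of erythroid cells, of an even fall of B cell genes and of the splits behind list medians were chosen only after the results were seen, as were the list tests of the difference between tissues; the tests of single libraries, of a batch and of the interaction genes were chosen before. For list medians 1 of 35, the real split alone, is the smallest share possible, and the real split was the largest for 4 of 37 lists in bone marrow and 8 of 37 in spleen; the lists weighed here were picked from these after the results were seen.

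Genes that glucocorticoids induce were higher in both tissues, with list medians of 0.82 in bone marrow and 1.11 in spleen. With camera at an estimated correlation neither was called (adjusted p = 0.363 and 0.211). Fry called the list higher in both tissues (adjusted p = 7.23e-04 and 2.19e-04). Each median was the largest in size of 35 splits of the libraries (highest other 0.589 and 0.730). With genes shared with the glucocorticoid list left out, no cell type list had a median as high. The nearest was 0.224 in bone marrow (NK cell) and 0.467 in spleen (immature neutrophil). The widest upper bound among cell type lists was 0.655 and 0.679. These bounds take a list's genes as independent, which they are not, and leave out the spread between libraries. They therefore do not exclude a changed cell mix as the whole cause. A single library is excluded, since at least 13 of 16 called members in bone marrow (without hM3Dq replicate 7) and 15 of 16 in spleen (without hM3Dq replicate 8) kept their call. A batch that follows the replicate numbers cannot be told apart from the virus, because 0 numbers occur in both virus groups. Activation of the neurons followed by a rise of glucocorticoid hormone may be behind the pattern. The hormone was not measured in the data used here, and a batch and a changed cell mix stay open.

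Interferon-response genes were lower in both tissues, with list medians of -0.63 in bone marrow and -0.71 in spleen. With camera at an estimated correlation neither was called (adjusted p = 0.768 and 0.399). Fry called the list lower in spleen (adjusted p = 0.00918) but not in bone marrow (0.0744). Each median was the largest in size of 35 splits (highest other size 0.555 and 0.627). Fewer erythroid cells as the whole cause are argued against: with the haemoglobin share in the model the interferon median was -0.672 in bone marrow and -0.658 in spleen, while the erythroid median went from -0.782 to -0.156 and from -0.524 to 0.226. A single library is excluded as the source of the medians, those nearest 0 being -0.521 and -0.597, both without mCherry replicate 4. Calls of single genes in bone marrow were less stable. Of the 5 called there, those of Isg15, Usp18 and Cmpk2 ended without mCherry replicate 4. A changed mix of other cells cannot be told apart from a response of the same cells. Without the covariate the erythroid list was nearest at -0.782 in bone marrow and -0.524 in spleen. With it the lowest cell type medians were -0.346 (stromal and endothelial) and -0.397 (mature B cell). The short CD4 T cell list, of 6 and 7 genes with medians of -0.165 and -0.309, has lower bounds of -0.829 and -0.857, below the interferon medians. The pan T cell list of 24 genes has bounds of -0.0725 and -0.280, above them. A lower interferon tone after the neurons were activated stays open beside a changed mix, as does a batch.

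Mature B cell genes were lower in spleen, with a list median of -0.44, the largest in size of 35 splits (highest other size 0.327). The list was not called by camera with an estimated correlation (adjusted p = 0.399) and was called lower by fry (adjusted p = 0.00918). Some of the genes were lower in bone marrow too: Fcer2a (-0.94, called), and Cr2 (-0.70), Bank1 (-0.52) and Cd83 (-0.52), not called. There Ms4a1 was at 0.15, and 12 of the 20 genes were above 0. Cochran's Q argued against an even fall in spleen (p = 1.64e-23, n = 20 genes), but it takes the genes as independent, which they are not. In spleen Cr2 fell by 1.18 and Ms4a1 by 0.77, whereas Cd79b stood at -0.09 and Ighd at -0.07. Fewer B cells would give an even fall only if B cells alone carried these transcripts, which was not tested. Fewer B cells are therefore not excluded. A single library is excluded, the median nearest 0 being -0.381 without spleen hM3Dq replicate 6. Fewer B cells, a loss of some B cell subsets, or lower transcription of some B cell genes in the same cells may account for the pattern. The data used here do not separate them, and a batch stays open.

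Single libraries stood far from the other 3 of their group in 11 of 254 groups of values, where chance gives about 1 in 20 (12.7). S1pr1 was at 6.29 FPKM in bone marrow hM3Dq replicate 5 (others 4.52 to 4.62). Mxd1 was at 105 in bone marrow hM3Dq replicate 6 (91.6 to 93.4) and at 80.3 in bone marrow mCherry replicate 3 (66.3 to 68.3). Il1r2 was at 23.6 in bone marrow mCherry replicate 3 (16.4 to 17.5), and Tsc22d3 at 9.59 in bone marrow mCherry replicate 1 (15.7 to 16.9). Egr3 was at 8.58 in spleen hM3Dq replicate 5 (5.85 to 6.26), Cxcl9 at 1.06 in spleen hM3Dq replicate 7 (1.71 to 1.78) and Tagln at 5.32 in spleen hM3Dq replicate 6 (3.13 to 3.31). The haemoglobin share was 0.133% in spleen hM3Dq replicate 6 (1.17 to 1.33%). Cxcl10 was at 4.23 in spleen mCherry replicate 1 (0.979 to 1.34), and Pcna at 57.9 in the same library (45.9 to 47.8).

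The change differed between tissues, by the interaction, for 8 named genes. As bone marrow minus spleen the log2 differences were 1.19 for Samsn1, 1.06 for Ptp4a1, 1.36 for Pla2g3, 0.67 for Tank, -1.15 for Ppp1r21, -1.19 for Cxcr4, -1.69 for Bbc3 and -0.75 for Ccnd3. With a replicate block Samsn1, Ptp4a1, Pla2g3 and Tank were not called (adjusted p from 0.144 to 0.173). Camera on the interaction called 10 lists, none of them with an estimated correlation (lowest adjusted p = 0.814) and none with fry. Their median differences were 0.47 for cAMP and immediate early genes, 0.31 for T helper effector genes, 0.29 for mature B cell genes, 0.18 for monocyte genes and 0.11 for MHC class II presentation. They were -0.24 for mitochondrially encoded genes, -0.0781 for cytosolic ribosomal proteins, -0.49 for immature neutrophil genes, -0.34 for megakaryocyte genes and -0.20 for stromal genes.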

How the results depend on the processing

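Pseudocounts of 0.5 and 1, the FPKM filter of 0.5, voom, the haemoglobin covariate and list tests without composition scaling were chosen after seeing the data. The deposited unit is FPKM, and the DESeq2 Wald tests planned for counts were not run on the recovered reads. No called named gene changed direction in the alternatives or with a library left out. Values that lost their call numbered 106 of 964 for bone marrow, 165 of 1740 for spleen, 62 of 222 for the interaction and 0 of 160 between tissues; 12 of 294 and 13 of 335 values not called in bone marrow and spleen became called; 34 of 46, 57 of 83, 3 of 8 and 8 of 8 named called genes kept it throughout. Except for fewer genes tested, fewer libraries or a minimum fold change, the cause was not tested.

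Bone marrow calls numbered 192 with a minimum 2-fold change, 300 with no filter, 1530 in a single fit of all 16 libraries and 496 with the haemoglobin covariate, and 271 to 724 with 1 library left out. Spleen calls numbered 223 with a minimum 2-fold change, 600 with no filter and 2060 with quality weights, and 404 to 1693 with 1 library left out. Interaction calls numbered 11 without composition scaling, 42 with quality weights, 34 and 68 with pseudocounts of 0.5 and 1, 11 with the FPKM filter of 0.5 and 9 with the replicate block, and 3 to 37 with 1 library left out. The replicate block ended the calls of Samsn1, Ptp4a1, Pla2g3 and Tank (adjusted p 0.144 to 0.173). Residuals of the 2 tissues' libraries of the same number had r of 0.0372 to 0.336, 4 of 8 above 0.1, against -0.295 to 0.130 for other pairs. Of the bone marrow libraries 7 of 8 correlated best with their own number, a hint from the data, not the design, that numbers mark mice. Tissue calls numbered 5089 with a minimum 2-fold change and 11123 to 11904 with 1 library left out. Shared calls numbered 654 at an adjusted p below 0.10 and 89 to 327 with 1 number left out. Lists called numbered 0 with an estimated correlation in both tissues and 1 with fry in bone marrow, and 9 to 13 in bone marrow and 16 to 20 in spleen with 1 library left out. The haemoglobin covariate ended the oxidative phosphorylation and fatty acid oxidation lists in bone marrow (adjusted p up to 0.437) and the cell cycle and heat shock lists in spleen (up to 0.220). No composition scaling ended the same bone marrow lists (up to 0.197) and stromal in spleen (0.0666), pseudocount 1 fatty acid oxidation (0.0516) and stromal (0.0534), median-of-ratios scaling stromal (0.0576), and the FPKM filter of 1 megakaryocyte in spleen (0.137).

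None of the results whose sign turned was called in the main fits. The bone marrow pan T cell median (-0.05) was 0.0259 without composition scaling, 0.0433 with the haemoglobin covariate and -0.101 to 0.0435 with 1 library left out, above 0 without mCherry replicate 2 (0.0435) or 3 (0.00762). The bone marrow homing median (-0.03) was 0.0413 without composition scaling and -0.0794 to 0.0104 with 1 library left out (0.0104 without hM3Dq replicate 8). With the haemoglobin covariate the homing list was called lower, as given above. The bone marrow mature B cell median (0.06) was -0.0460 to 0.156, below 0 without mCherry replicate 1 (-0.0460) or 2 (-0.0433). Bone marrow Ccr7 (0.03) was -0.0278 with quality weights, -0.0698 with the haemoglobin covariate and -0.0785 to 0.0937 with 1 library left out, below 0 without hM3Dq replicate 6 (-0.0785) or mCherry replicates 2 (-0.0265) and 3 (-0.00876). Bone marrow Nr3c1 (0.07) was -0.0705 with the covariate. Spleen Ccr7 (0.06) was -0.00500 with the covariate and -0.00301 to 0.132 with 1 library left out (-0.00301 without hM3Dq replicate 6). The spleen erythroid median (-0.52) was 0.226 with the covariate. Spleen Ighd (-0.07) was -0.127 to 0.0149, above 0 without mCherry replicate 4.

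Calls of genes named above ended as follows with 1 library left out, where h stands for an hM3Dq and m for an mCherry replicate and the range is that of the adjusted p. In bone marrow these were Isg15 (all but h7, 0.0518 to 0.115), Cmpk2 (h6, h8, m4, 0.0518 to 0.0609), Usp18 (h6, h8, m3, m4, 0.0519 to 0.0676), Nfil3 (h8 and all m, 0.0618 to 0.0886) and Cry2 (all but h5, 0.0554 to 0.0984). The others were Cxcl2 (all but h5, 0.0521 to 0.0824), Cpt2 (all but h7, 0.0522 to 0.110), Cox6a2 (h5, h7, h8, m2, m3, m4, 0.0674 to 0.109), Herpud1 (h7, m1, m2, m4, 0.0505 to 0.0669) and Fcer2a (h6, m2, m4, 0.0518 to 0.0639). Of the lists, plasmacytoid dendritic cell ended without h5, h8 or m4, fatty acid oxidation without h5, h8, m2 or m3, and oxidative phosphorylation without h5, m2 or m3 (adjusted p up to 0.223).

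In spleen they were Cxcl9 (all but m4, 0.0557 to 0.120), Gp1ba (all but m3, 0.0541 to 0.113), Vcam1 (all but m3, 0.0643 to 0.101), Cd209a (all but h5, 0.0568 to 0.120) and Cry2 (all but h5, 0.0525 to 0.107). They were also Tef (h6, h7, h8, m1, m2, m4, 0.0546 to 0.0853), Bmf (the same libraries, 0.0541 to 0.0787), Ctla4 (h7, h8 and all m, 0.0571 to 0.101) and Ccl4 (h7, h8, m2, m3, m4, 0.0576 to 0.0724). The last were Tagln (h7, h8, m1, m3, m4, 0.0553 to 0.0709), H2-DMb2 (h8, m2, m3, m4, 0.0540 to 0.0737) and Ifng (h8, m1, m4, 0.0546 to 0.0598). Of the lists, megakaryocyte ended without h7, m2, m3 or m4, stromal without h7, m1 or m4, monocyte without h6, m2 or m3, heat shock without h6 or m1, chemokines without m2 or m3, immature neutrophil without h5 or m3, and MHC class II without m3 (adjusted p up to 0.261).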

Other observations

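The genes of this part were chosen only after their values were seen, whereas its tests, of the erythroid and cell cycle lists and of the splits behind counts, were chosen before.

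Of the 288 genes called in the same direction in both tissues, some are given here, with the log2 change in bone marrow, then spleen (limma, adjusted p below 0.05 in both). The size of the change could differ: Ston1 (1.99, 3.88) was also called by the interaction (-1.81, adjusted p = 0.0398). Higher in both were Pik3ip1 (2.12, 1.85), which restrains PI3-kinase, Dusp1 (2.59, 1.87), Klf9 (2.17, 1.75), Sik1 (1.28, 1.92), a kinase that restrains CREB-dependent transcription, Pdcd4 (1.00, 1.24), an inhibitor of translation, and Ptpn22 (0.73, 1.67), a phosphatase that dampens antigen receptor signalling. The cytokine receptor gene Lifr rose by 1.37 and 1.80, and Pnpla2, the fat-splitting lipase ATGL, by 0.87 and 0.85. Lower in both were Dynll1 (-0.92, -1.11), Spice1 (-1.02, -0.84) and Nfya (-0.47, -0.80), a subunit of the CCAAT-binding factor.

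The erythroid and cell cycle lists moved together across libraries, and 2 relations were computed. In bone marrow Pearson's r over 8 libraries was 0.966 (exact permutation p = 0.00494, adjusted p = 0.00494) and Spearman's rho 0.595 (exact permutation p = 0.132), but r was 0.308 without the 2 libraries farthest from the median, so that relation rests on those libraries. In spleen r was 0.916 (exact permutation p = 5.95e-04, adjusted p = 0.00119), rho 0.881 (exact permutation p = 0.00724), and r was 0.855 without the 2 farthest. Around the group means r was 0.954 and 0.923. Erythroid precursors may carry part of the cell cycle signal, which remains a hypothesis.

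Other splits of the libraries were fitted in the same way. Of 35 splits, 1 (the real one) called as many genes in bone marrow (781, highest other 1), in spleen (1368, highest other 1), between tissues (11740, highest other 0) and in both tissues at once (288, highest other 1). That is the smallest share 35 splits allow. Every other split mixes the real groups, so a real difference enters the spread and lowers the count. The low counts of the other splits therefore do not by themselves exclude chance. For the interaction 2 of 100 splits called as many genes as the real 17. The other called 227 and kept the bone marrow labels while only 1 of the 4 spleen hM3Dq libraries kept its label. It thus adds effects the tissues share and points to that structure of the samples. The 100 splits relabelled each tissue separately and so ignored the replicate numbers, which may mark mice. For the number of lists chance is not excluded: 14 of 35 splits in bone marrow gave as many as the real 11 (highest other 20) and 3 of 35 in spleen as many as the real 19 (highest other 20).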
